A study of Mus musculus with 6 samples.

How the data were processed

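The series profiled RNA of sorted mouse retinal cells in 6 libraries, 3 labelled CD36 flox and 3 labelled CD36 CKO, a conditional knockout of the fatty acid and lipoprotein scavenger receptor CD36. Retinae were dissociated, stained for CD45 and CD11b, and cells with intermediate CD11b and positive CD45, the gate named as microglia, were sorted for Smart-seq2-type full-length cDNA libraries, per the labels' protocols. The protocol also describes intravenous sodium iodate, an oxidant that injures the retinal pigment epithelium, at 20 mg/kg with buffer-injected controls and collection after 7 days. No label used here says which treatment a library had or which Cre driver was used.

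One table of estimated counts per gene symbol, made by the authors and deposited unscaled, was used; its values have up to 2 decimals. Reads were trimmed with fastp 0.18.0 and aligned with HISAT2 2.2.4 to mm10, per the submitters' processing notes; the counting tool, annotation and strand setting are not given in the sources used here. Without a stated strand setting, overlapping and antisense genes cannot be separated, and near-identical genes (the haemoglobin genes, the Ugt1a cluster and the Ly6 family) have uncertain values. The table held 21956 rows, of which 83 without a symbol were left out of library sizes and tests (0.0122% to 0.0185% of counts). Another 22 repeated-symbol rows were summed, which left 21851 genes. Estimated counts were rounded to whole numbers before testing. Symbols were placed on GRCm38, the assembly behind mm10, with the GENCODE M21 annotation, and 7 list symbols were matched through another name of the gene.

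The total per library was 19682735, 18743897 and 14936446 counts for flox 1 to 3 and 16149808, 13462683 and 20018910 for CKO 1 to 3. A count of 0 allows up to 3 counts, or 0.150 to 0.223 CPM (counts scaled to a common library total) at these depths. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. Groups and replicate numbers came from the titles. The description codes of flox 2 and flox 3, and of CKO 2 and CKO 3, differ only in OD against OS, so each pair can hold both eyes of 1 mouse. If so, p-values over 3 libraries against 3 are too small, and fits with such libraries summed or linked are among the alternatives.

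The main test was edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr, a robust quasi-likelihood fit on the group alone and Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are CKO against flox with a prior count of 0.125, and CPM values of single genes are TMM-scaled. Gene lists were tested with camera (limma 3.58.1) on log-CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, for lists with at least 5 tested members, adjusted by Benjamini-Hochberg over 31 lists. Quality measures and summed CPM of marker lists were compared by two-sided exact permutation tests, whose smallest p with 3 against 3 is 0.1. Library similarity was described with Pearson correlations and with principal components of the 1000 most variable genes.

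The 32 gene lists, the tests, the main design and most alternatives were fixed before the data were examined. So was the rule for named genes. It took Cd36, Nlrp3 and Il1b always, and up to 4 tested members of smallest p per list. If under 5 genes pass, it also took the 10 of smallest p, as values only, without predicted models and sex-linked genes. Other genes named here were chosen after their values were seen. The values of 1 member of the monocyte list are not reported here. Other settings fixed at that time were 3 other scalings, 2 other count filters, DESeq2 1.42.0, limma-voom with sample weights, a threshold of 0.1, a fold threshold, a prior count of 2, libraries of a shared code summed or linked as a random block, the title number as a block, each library left out, an estimated inter-gene correlation and fry. Fits with a batch term, fits without sex-linked genes and within-batch ratios were added after seeing the data. The batch is defined by haemoglobin: libraries above 100 CPM are called haemoglobin-positive and the others haemoglobin-negative.

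The tests were tried on simulated counts for 13477 genes with the means, library sizes and dispersions of these libraries. Changed genes were drawn from the more abundant genes only. Libraries were simulated as independent, with no batch and no shared mouse, so recovery in the real comparison can be lower than given here. In the CKO against flox comparison edgeR recovered 20 of 100 genes changed 2-fold and 91 of 100 changed 4-fold, and called 16 unchanged genes. DESeq2 recovered 39 and 97 and called 59 unchanged genes. At a much lower simulated dispersion both recovered 100 of 100 at either fold.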

Results

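The data are 6 RNA-seq libraries of CD11b-intermediate, CD45-positive cells sorted from mouse retina, 3 labelled flox and 3 labelled CKO. Each held between 13462683 and 20018910 counts and 15172 to 16092 genes with a count. The series title joins CD36, lipid accumulation in reactive microglia and the Nlrp3 and IL-1β pathway, so the comparison asks how expression in these cells differs when Cd36 is deleted.

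Cd36, the targeted gene, was still counted in every library. Its level was 90.5, 193 and 144 CPM in flox 1 to 3 (mean 142 ± 51.3, SD, n = 3) and 122, 65.2 and 28.5 CPM in the libraries labelled CKO 1 to 3 (72.0 ± 47.2). The library labelled CKO 1 therefore held more Cd36 than the library labelled flox 1, and directions below refer to the labels. Cd36 lies on chromosome 5 at 17781690 to 17888801 (minus strand, GRCm38), and counts per gene do not show whether a deleted exon is missing. The log2 fold change was -0.98 (SE 0.51), with an adjusted p of 0.9996 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Without CKO 1, which leaves only haemoglobin-negative CKO libraries, it was -1.61, and without CKO 3 it was -0.60. Within the haemoglobin-negative batch the log2 ratio was -0.95 and within the haemoglobin-positive batch -0.46. Its levels also parted by batch, at 28.5 to 90.5 CPM in the haemoglobin-negative and 122 to 193 CPM in the haemoglobin-positive libraries.

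Nlrp3, the sensor of the NLRP3 inflammasome (chromosome 11, 59541568 to 59566956), stood at 20.6 ± 9.39 CPM in the flox libraries and 11.9 ± 1.33 in the CKO libraries (SD, n = 3 each). All 3 CKO values (10.5, 13.1 and 11.9 CPM) lay under the 3 flox values (15.4, 31.5 and 15.0 CPM). Il1b, which encodes interleukin-1β (chromosome 2, 129364570 to 129371139), spanned 74.9 to 507 CPM within flox and 166 to 502 CPM within CKO. Neither gene passed the test: the log2 fold change of Nlrp3 was -0.80 (SE 0.33) and that of Il1b 0.23 (SE 0.66), both with an adjusted p of 0.9996 (edgeR, Benjamini-Hochberg). For Nlrp3 the unadjusted p was 0.0396, and its fold change was -0.36 without flox 2. The within-batch log2 ratios (haemoglobin-negative, then haemoglobin-positive) were -0.29 and -1.15 for Nlrp3 and -0.15 and -0.32 for Il1b. Il1b turned to -0.24 with the batch as a term and to -0.25 with libraries of a shared code summed.

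**Figure D1:**
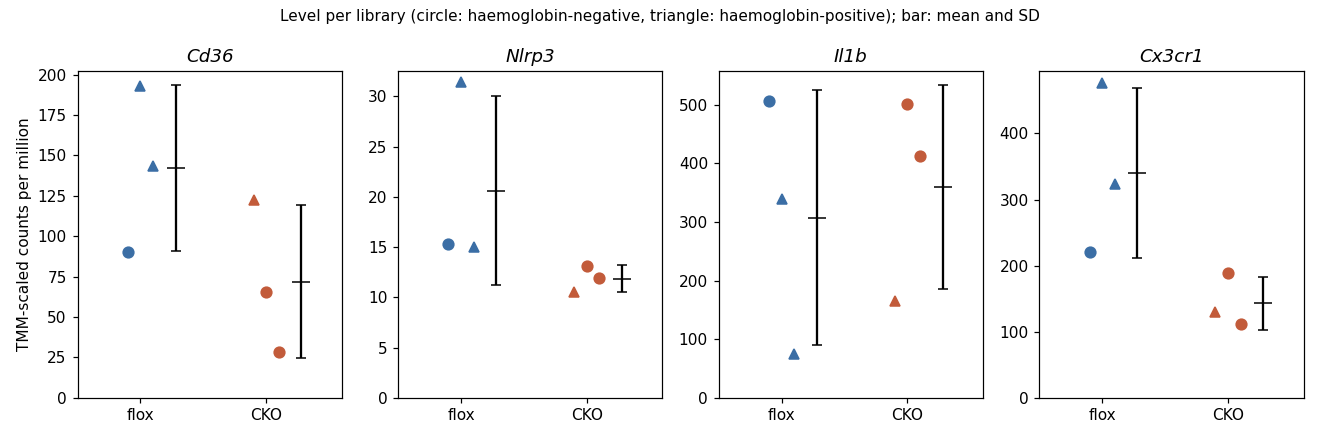
TMM-scaled CPM of Cd36, Nlrp3, Il1b and Cx3cr1 (vertical axes) in each flox and CKO library, with circles for haemoglobin-negative and triangles for haemoglobin-positive libraries and bars for the mean and SD. The 3 CKO values of Nlrp3 and Cx3cr1 lie under all 3 flox values, while those of Cd36 and Il1b overlap.

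Across the genome no gene passed the main test. The genes of smallest p included Tmem100, a transmembrane protein gene (chromosome 11, 90030348 to 90036508), at 8.82 ± 5.64 CPM in flox and 0.183 ± 0.114 in CKO. Trf, which encodes the iron carrier transferrin (chromosome 9, 103204001 to 103230444), stood at 350 ± 27.1 against 580 ± 34.2 CPM. The adhesion receptor gene Adgre5 (chromosome 8, 83723251 to 83741326) stood at 18.8 ± 3.13 against 44.8 ± 11.04 CPM. Ch25h, the enzyme that makes 25-hydroxycholesterol (chromosome 19, 34473778 to 34475164), stood at 36.4 ± 9.05 against 14.4 ± 4.401 CPM.

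The other 6 by the same rule were Sox30, Ugt1a6b, Pagr1a, Faxdc2, Wdfy1 and F10. Sox30 had 0, 10 and 3 counts in flox and 174, 64 and 147 in CKO. Pagr1a stood at 10.7 ± 4.12 CPM in flox and 1.95 ± 1.14 in CKO, and Wdfy1 at 20.4 ± 1.57 and 36.9 ± 5.34. Ugt1a6b had 35, 27 and 114 counts in flox and 0 in each CKO library, but shares exons with its gene cluster and is uncertain. F10, the gene of coagulation factor X, had 0, 2 and 3 counts in flox and 52, 42 and 34 in CKO, and Faxdc2 had 1, 0 and 1 against 29, 16 and 26. The flox and CKO ranges of these 10 genes did not overlap (n = 3 each).

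edgeR tested 13477 genes and called 0 at an adjusted p of 0.05, with 379 at an unadjusted p under 0.05 (195 higher and 184 lower in CKO, where chance gives 674). DESeq2 called 23 genes (13 higher, 10 lower), 3 of them Y-linked, with 581 at an unadjusted p under 0.05. These 23 held 8 of the 10 genes above, and 17 were also called by DESeq2 with the batch as a term. In the simulation DESeq2 made more calls among unchanged genes (59) than edgeR (16). The 2 groups did not overlap for 1078 of 13477 genes (7.999%), where chance gives 10%.

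Homeostatic microglial genes, which mark resting microglia, were mixed: 9 of 22 had a positive and 13 a negative fold change. The fractalkine receptor gene Cx3cr1 (chromosome 9, 119901616 to 120069879) stood at 221, 476 and 323 CPM in flox and 130, 188 and 111 in CKO. Its log2 fold change was -1.25 (SE 0.31, unadjusted p 0.00392 by edgeR), with within-batch log2 ratios of -0.56 (haemoglobin-negative) and -1.62 (haemoglobin-positive). Sall1, a microglial transcription factor gene, stood at 11.7 ± 9.34 against 1.52 ± 0.339 CPM, and lay higher in CKO within the haemoglobin-negative batch (log2 ratio 0.80) and lower within the other (-3.88). Among 26 disease-associated microglial genes, induced in phagocytic lipid-loaded states, 14 were positive and 12 negative. Apoe, the apolipoprotein E gene, stood at 13521 ± 1885 against 27015 ± 13811 CPM and Lpl, the lipoprotein lipase gene, at 117 ± 23.1 against 58.1 ± 33.4. Adjusted over the list alone, 0 homeostatic genes and 1 disease-associated gene (Ch25h, adjusted p = 0.0427 by edgeR with Benjamini-Hochberg adjustment) passed. Adjusted over all genes, 0 passed. Neither list passed camera (adjusted p = 0.234 and 0.849), though the homeostatic list passed as lower without flox 1 (7.76e-06) and without CKO 2 (0.0338), and the mean fold change of the disease-associated list (-0.08) opposed its median (0.00347) and its test direction.

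Lipid genes were mixed in direction. In the cholesterol efflux and nuclear receptor target list, 12 of 20 members were positive, and Apoc2, an apolipoprotein gene, stood at 101 ± 12.4 CPM in flox and 305 ± 138 in CKO. Apoc2 (higher) and Ch25h (lower) passed when adjusted over the list alone (adjusted p = 0.0189 for both, edgeR with Benjamini-Hochberg adjustment), and 0 passed over all genes. Apoe differed in the haemoglobin-negative batch (log2 ratio 1.14) and hardly in the other (0.01). Lipid droplet genes were positive in 13 of 20, with the acyl-CoA synthetase gene Acsl4 at 46.5 ± 3.12 against 36.1 ± 5.95 CPM and the diacylglycerol acyltransferase gene Dgat2 at 4.98 ± 0.494 against 7.44 ± 2.34. Uptake genes other than Cd36 were positive in 12 of 18, with Cd5l at 3.18 ± 1.57 against 1.03 ± 0.365 CPM, and their mean (-0.06) opposed their median (0.09). Cholesterol synthesis genes were negative in 14 of 19, led by Sc5d at 24.4 ± 2.05 against 18.2 ± 2.33 CPM and Cyp51 at 22.6 ± 2.94 against 16.4 ± 3.28. Fatty acid oxidation genes split 9 to 10, with Acadl at 80.4 ± 7.36 against 64.2 ± 12.3 CPM. In the last 4 lists 0 genes passed over the list alone or over all genes, and none of the 5 lists passed camera (adjusted p = 0.241 for lipid droplets, 0.803 for uptake, 0.453 for efflux, 0.356 for synthesis and 0.849 for oxidation), with efflux passing without CKO 1 (0.0286).

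Inflammasome and IL-1 genes split 11 positive to 8 negative. Il1rn, which encodes the IL-1 receptor antagonist, stood at 22.1 ± 7.27 CPM in flox and 61.6 ± 28.4 in CKO, and Txnip, an NLRP3-binding thioredoxin inhibitor, at 128 ± 32.2 against 209 ± 62.2. Inflammatory cytokine and NF-κB genes split 13 to 12, with the co-stimulatory receptor gene Cd40 at 18.1 ± 9.92 against 37.5 ± 9.11 CPM and the chemokine gene Ccl2 at 389 ± 225 against 224 ± 33.4. Interferon response genes were positive in 9 of 22, with Mx1 at 49.8 ± 1.61 against 32.3 ± 13.6 CPM. Bst2, Ifi27l2a and Irf7, the other interferon genes named by the rule, had positive log2 fold changes (0.50, 0.42 and 0.34). In these 3 lists 0 genes passed over the list alone or over all genes, and the camera adjusted p was 0.803, 0.817 and 0.803. With the batch as a term the interferon list passed as lower (adjusted p = 0.0150, and 0.939 with an estimated correlation), as it did with codes summed (0.0195) and without CKO 2 (4.35e-04).

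Cell cycle genes were lower in CKO as a list: all 27 tested members had a negative fold change, with a median of -0.39 (camera adjusted p = 3.81e-06, but adjusted p = 0.928 with an estimated correlation). Ccne2, a cyclin of the G1 to S transition, stood at 20.5 ± 5.44 CPM in flox and 9.74 ± 3.16 in CKO, Mcm4, a subunit of the replicative helicase, at 49.7 ± 11.4 against 31.2 ± 3.17, and Top2a at 93.0 ± 28.5 against 61.9 ± 9.51. The summed level of the list was 2119, 2649 and 1847 CPM in flox 1 to 3 and 2163, 1356 and 1352 CPM in CKO 1 to 3, so that CKO 1 lay within the flox range. The log2 ratio of these sums was -0.65 in the haemoglobin-negative batch and -0.06 in the other. Genes of MHC class II and co-stimulation were higher as a list, with 9 of 10 positive and a median of 0.93 (camera adjusted p = 3.00e-04, but adjusted p = 0.928 with an estimated correlation). Cd74, the invariant chain gene, stood at 5666 ± 3304 against 11596 ± 6908 CPM, and the median was 0.40 with the batch as a term. The summed level of this list followed the batch, at 19741, 31585 and 22919 CPM in flox 1, CKO 2 and CKO 3 against 6655, 8857 and 8884 CPM in flox 2, flox 3 and CKO 1. Of either list 0 members passed over the list alone or over all genes. The MHC class II call was also lost without CKO 2 (adjusted p = 0.0963) and with libraries of a shared code summed (0.111).

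Mitochondrially encoded genes were higher in CKO in 13 of 13 (median 0.34, camera adjusted p = 1.52e-04, but adjusted p = 0.928 with an estimated correlation), with mt-Co3 at 5099 ± 302 against 7010 ± 1640 CPM. Their share of counts was 8.70% in CKO 1 and 4.85% to 6.02% in the other 5 libraries, and without CKO 1 the adjusted p was 0.1996. The log2 ratio of the summed level was -0.07 in the haemoglobin-negative batch and 0.68 in the other. Nuclear oxidative phosphorylation genes were positive in 24 of 33, with Ndufa1 at 132 ± 8.01 against 176 ± 25.01 CPM (camera adjusted p = 0.0781). Immediate early genes, which cell dissociation also induces, were negative in 17 of 21, with the transcription factor gene Klf2 at 94.3 ± 56.9 against 36.1 ± 3.09 CPM (adjusted p = 0.0629). With the batch as a term these 2 lists passed (adjusted p = 0.0114 and 2.67e-04, and 0.921 for both with an estimated correlation), as they did with codes summed and without flox 3, CKO 2 or CKO 3. Glycolysis genes were negative in 12 of 18 (Pdk1 29.4 ± 3.51 against 20.3 ± 1.14 CPM), phagocytosis and lysosome genes positive in 22 of 30 (Psap 2169 ± 336 against 2891 ± 719 CPM), and oxidative and ER stress genes positive in 15 of 20 (Slc7a11 5.59 ± 1.94 against 18.5 ± 11.02 CPM). The last 3 lists had camera adjusted p-values of 0.234, 0.244 and 0.382, and the first pair passed without CKO 1 (1.01e-04 and 0.00461). Of any list in this paragraph 0 members passed over the list alone or over all genes.

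**Figure D2:**
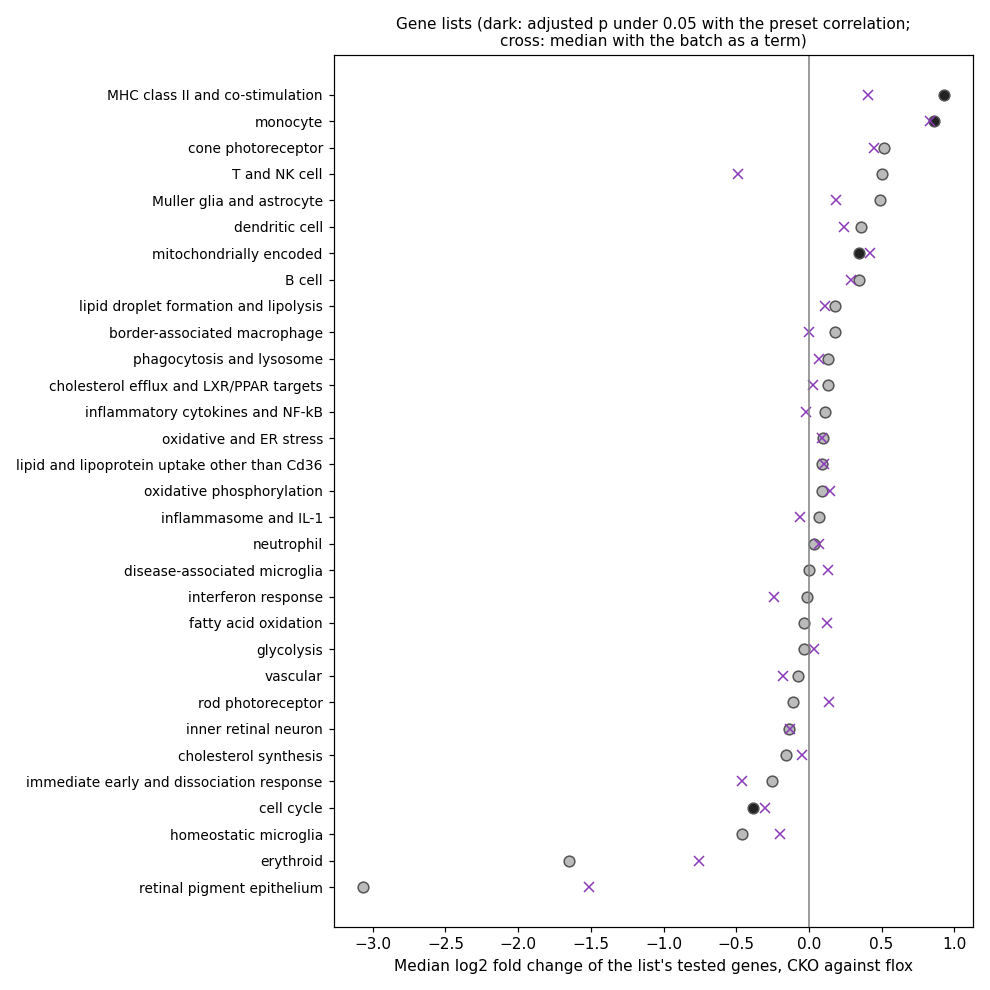
Median log2 fold change, CKO against flox (horizontal axis), of the tested genes of 31 gene lists (vertical axis), with dark points for an adjusted p under 0.05 at the preset correlation and crosses for the median with the batch as a term. The 4 dark points are the MHC class II, monocyte, mitochondrially encoded and cell cycle lists, and 0 lists passed with an estimated correlation.

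Markers of monocytes, blood cells that can enter the gate, were higher in CKO as a list. Of 14 members 12 were positive, with a median of 0.86 (camera adjusted p = 2.97e-07, but adjusted p = 0.161 with an estimated correlation). S100a4, a calcium-binding protein gene, stood at 21.7 ± 4.27 CPM in flox and 39.7 ± 6.16 in CKO, and Hp, the haptoglobin gene, at 3.21 ± 1.55 against 9.93 ± 4.48. Adjusted over the list alone 5 members passed (smallest adjusted p = 0.0226, edgeR with Benjamini-Hochberg adjustment), and 0 over all genes. The summed level of the list, which its most abundant members set, was 1607 ± 553 against 1765 ± 435 CPM (exact permutation p = 0.8, n = 3 each). Within the haemoglobin-negative batch that sum was lower in CKO (log2 ratio -0.17), and within the haemoglobin-positive batch it hardly differed (0.03).

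Retinal transcripts were present in all 6 libraries: the summed level of rod photoreceptor genes was 9867 to 27988 CPM, with no separation by label (exact permutation p = 0.8). That level did part by batch, at 9867 to 11564 CPM in the haemoglobin-negative and 15971 to 27988 CPM in the haemoglobin-positive libraries. Rods (12 of 16 negative, Rp1 364 ± 183 against 218 ± 130 CPM), cones (8 of 10 positive, Gngt2 292 ± 15.6 against 374 ± 81.8) and inner retinal neurons (9 of 14 negative, Rbpms 6.93 ± 0.953 against 9.36 ± 0.907) had camera adjusted p-values of 0.286, 0.946 and 0.817. The cone list's median (0.51) and mean (0.47) opposed its test direction. Müller glia and astrocyte genes were positive in 12 of 12 (Rlbp1 44.3 ± 20.2 against 80.0 ± 61.5 CPM, adjusted p = 0.0629). Pigment epithelium genes were negative in 5 of 7, with a summed level of 336 CPM in flox 3 and 18.1 to 81.3 CPM in the other 5 libraries (adjusted p = 0.160). Vascular genes were negative in 10 of 15 (Esam 12.7 ± 7.87 against 4.25 ± 3.37 CPM, adjusted p = 0.234). With 1 library left out some of these lists passed: Müller without flox 1, flox 2, CKO 1 or CKO 2, rods without flox 1 or CKO 1, pigment epithelium without flox 1 or CKO 2, vascular without flox 3, and cones without CKO 2.

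Among other immune lists, border-associated macrophage genes were positive in 6 of 11 (Ms4a7 530 ± 200 against 1116 ± 646 CPM, adjusted p = 0.453), and neutrophil genes in 4 of 7 (Mmp8 2.34 ± 0.594 against 0.853 ± 0.718, adjusted p = 0.445). T and NK cell genes were positive in 9 of 16 (Cd2 1.88 ± 1.91 against 5.96 ± 1.41, adjusted p = 0.849), B cell genes in 4 of 6 (Cd79b 13.2 ± 6.14 against 22.3 ± 9.23, adjusted p = 0.204) and dendritic cell genes in 5 of 8 (Fscn1 9.07 ± 4.41 against 15.1 ± 3.39, adjusted p = 0.0781). The neutrophil list's median (0.03) opposed its mean (-0.08) and test direction, and the B cell list's mean (-0.05) opposed its median (0.34) and test. Erythroid genes were negative in 5 of 5 (Alas2 9.55 ± 11.3 against 1.14 ± 1.98, adjusted p = 0.0781). This list holds the haemoglobin genes that set the batch, so its value with the batch as a term is not read as a result. With 1 library left out the dendritic and erythroid lists passed without flox 1 or CKO 1, B cells without flox 2, T and NK cells without CKO 1 and neutrophils without CKO 3. In the retinal, vascular and immune lists other than the monocyte list, 0 genes passed over the list alone or over all genes.

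Y-linked transcripts differed between the labels. Ddx3y, Eif2s3y, Uty and Kdm5d summed to 153, 10.7 and 31.2 CPM in flox 1 to 3 (3007, 201 and 466 counts) and to 0.433, 0.594 and 0.749 CPM in CKO 1 to 3 (7, 8 and 15 counts). All 4 passed adjusted over the list alone (smallest adjusted p = 6.68e-04, edgeR with Benjamini-Hochberg adjustment) and 0 over all genes. With the batch as a term, Ddx3y and Eif2s3y were the 2 genes that passed over all genes, both lower in CKO (adjusted p = 0.00253 and 0.00626, edgeR). No label used here gives the sex of the mice. Xist, also on the sex-linked list, was not among the genes counted and could not be examined.

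Of 5 quality measures 1 separated the labels. The 50 most abundant genes held 24.98% ± 0.0968 of counts in flox and 28.4% ± 1.85 in CKO (exact permutation p = 0.1, the smallest that 3 against 3 allows). Total counts, genes with a count, and mitochondrial and ribosomal protein shares had exact permutation p-values of 0.4 to 0.7. Log-CPM values correlated at 0.896 to 0.952 between libraries, and no pair agreed within sampling noise.

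The largest difference between the libraries did not follow the labels. Principal component 1 (42.4% of variance) set flox 1, CKO 2 and CKO 3 apart from flox 2, flox 3 and CKO 1. Haemoglobin genes summed to 0.0743 to 0.356 CPM in the first 3 libraries and to 1862 to 4368 CPM in the others. The first 3 also held 251 to 293 CPM of a set of oocyte transcripts, against 1.76 to 4.02 CPM in the others. This set was picked after its values were seen, so its separation is a description and not a test. The second list of oocyte markers, written down before its values were looked at, summed to 148 to 174 CPM against 116 to 131 CPM. Most of that sum was Rnf114, at 109 to 162 CPM across the libraries. Each of these batches holds both labels, with 1 flox and 2 CKO libraries in the haemoglobin-negative batch and 2 flox and 1 CKO in the other. In each batch the 2 libraries of the same label share a description code before OD or OS. If each code is 1 mouse, every within-batch ratio compares 1 mouse with 1 mouse. Batch and animal then cannot be separated, and p-values of fits with the batch term are too small.

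**Figure D3:**
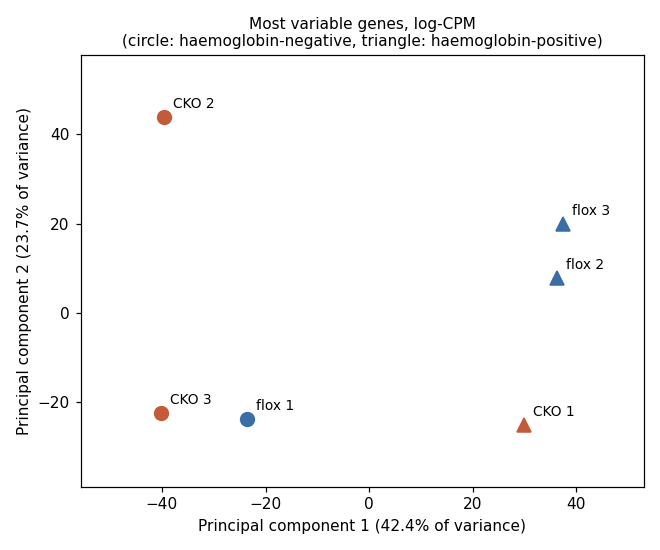
Scores on principal components 1 (42.4% of variance) and 2 (23.7%) of the log-CPM of the 1000 most variable genes, with blue for flox, red for CKO, circles for haemoglobin-negative and triangles for haemoglobin-positive libraries. Component 1 separates circles from triangles, and each side holds both labels.

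**Figure D4:**
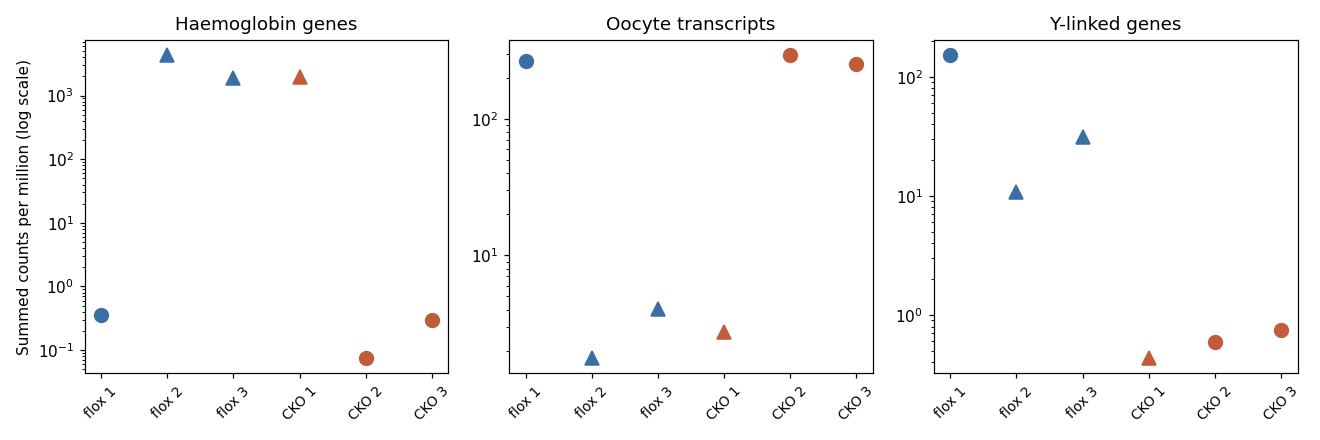
Summed CPM (vertical axes, log scale) of haemoglobin genes, oocyte transcripts and Y-linked genes in each of the 6 libraries, coloured by label (blue flox, red CKO), with circles for haemoglobin-negative and triangles for haemoglobin-positive libraries. The oocyte transcripts shown were picked after their values were seen. Haemoglobin is at or under 0.356 CPM where the oocyte transcripts are at 251 CPM or more, and the Y-linked sum is under 1 CPM in the CKO libraries only.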

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

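The fits with a batch term and without sex-linked genes were chosen after seeing the data; the other settings were planned. The edgeR count of 0 genes was also 0 under every other scaling, filter, threshold and replicate setting run, including each library left out, and the exceptions were DESeq2 (23 genes), the batch term (2, both Y-linked, and 0 without sex-linked genes) and DESeq2 with the batch term (45). The title numbers did not pair the libraries (correlations of -0.32, 0.01 and -0.33 for same-numbered libraries): with the replicate block 0 genes and 4 lists passed, and the block changed no call. Depth limits genes near the floor of 0.150 to 0.223 CPM, and dispersion (biological coefficient of variation 0.395) limits the rest. In the simulation, which gave each gene its own dispersion, edgeR found 20 of 100 2-fold changes among more abundant genes. The simulation held no batch and no shared mouse, so recovery in the real comparison can be lower. Cd36 kept its direction in all settings, from -1.61 to -0.60 with 1 library left out.

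Of 31 lists, 4 passed as reported. Among all 31, 0 passed with an estimated correlation, 0 with fry (directional or mixed), 8 with the batch term (the erythroid list among them, whose haemoglobin genes set the batch), 0 with the batch term and an estimated correlation, and 6 to 11 with 1 library left out. The 4 reported lists all passed with the batch term, and the monocyte and cell cycle lists passed with each library left out. The adjusted p with an estimated correlation was 0.928 for the MHC class II, cell cycle and mitochondrially encoded lists and 0.161 for the monocyte list. With the batch term as well it was 0.921, 0.939, 0.921 and 0.372 in that order, and with fry 0.987 for the first 3 and 0.598 for monocytes. The MHC class II list had 0.111 with libraries of a shared code summed and 1.7e-05 to 0.0963 with 1 library left out, and the mitochondrially encoded list 2.1e-06 to 0.1996. The number of other-cell-type lists whose summed levels separated the labels, 0 of 13, was 0 to 5 with 1 library left out (4 without flox 1, 5 without CKO 1, 1 without flox 2 or CKO 2). The cause was not tested, beyond fewer libraries where 1 was left out.

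Lists not called as reported passed camera with the preset correlation under some settings, in the direction reported unless stated (adjusted p). Without flox 1 these were homeostatic (7.76e-06), Müller (0.00315), pigment epithelium (4.1e-05), rods (0.0172), dendritic (9.86e-04) and erythroid (9.86e-04). Without flox 2 they were Müller (0.0178) and B cells (0.0455), and without flox 3 oxidative phosphorylation (0.0172), immediate early (4.67e-04) and vascular (0.0283). Without CKO 1 they were rods and glycolysis (1.01e-04 each), phagocytosis (0.00461), cholesterol efflux, T and NK cells and dendritic (0.0286 each), Müller (0.0212) and erythroid (0.00536). Without CKO 2 they were homeostatic (0.0338), interferon (4.35e-04), oxidative phosphorylation (0.0232), immediate early (0.0362), Müller (0.0248), pigment epithelium (0.00102) and, in the opposite direction, cones (0.0135). Without CKO 3 they were oxidative phosphorylation (0.0252), immediate early (0.00203) and neutrophils (0.0491). With codes summed interferon and oxidative phosphorylation (0.0195 each) and immediate early (0.00156) passed, and with no count filter pigment epithelium (0.0261). These passes depend on which libraries are kept, and their cause was not tested.

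Over the alternatives, 15 named genes and 18 lists turned direction at least once; none of them had passed the test as reported. The log2 fold change of Il1b was -0.25 with libraries of a shared code summed, -0.24 with the batch term, -0.22 by DESeq2 with the batch term and -0.23 to 0.80 with 1 library left out. With codes summed Nr2e3 stood at 0.023, Cnga1 at 0.084 and Pdc at 0.19, and Pdc at 0.14 with the batch term and 0.15 by DESeq2 with it. Cngb3 stood at -0.73 by limma-voom with weights and -0.027 with the code as random block, and Ms4a1 at 0.52 under the stricter filter. With 1 library left out the ranges were -0.86 to 1.71 for Arr3, -0.068 to 0.91 for Clu, -0.86 to 0.082 for Cnga1, -0.51 to 1.61 for Cngb3, -0.058 to 0.47 for Csf3r, -0.38 to 0.0060 for Cxcr2, -2.44 to 0.035 for Gzmb, -0.18 to 1.85 for Pax6, -0.84 to 0.13 for Pdc, -0.66 to 0.022 for Slc16a3, -0.54 to 0.10 for Slc2a1 and -1.35 to 0.10 for Tnf.

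The lists that turned are given by their adjusted camera p. With codes summed it was 0.434 for the inflammasome, cytokine and rod lists, 0.938 for cholesterol efflux, 0.756 for fatty acid oxidation, 0.131 for cones and 0.425 for T and NK cells. With the batch term it was 0.796 for the inflammasome, 0.659 for cytokines, 0.621 for fatty acid oxidation and cones, 0.133 for rods and 0.0610 for T and NK cells; with an estimated correlation as well it was 0.939 for the first 5 and 0.921 for T and NK cells. Fry gave 0.987 for cones and for T and NK cells, and the fit without a count filter 0.936 for inner retinal neurons. With 1 library left out the ranges were 7.8e-06 to 0.887 for homeostatic, 0.124 to 0.7998 for disease-associated, 0.1198 to 0.7998 for inflammasome, 0.0599 to 0.7998 for cytokine, 4.4e-04 to 0.960 for interferon, 0.316 to 0.971 for uptake, 0.0286 to 0.820 for cholesterol efflux, 0.370 to 0.943 for fatty acid oxidation, 1.01e-04 to 0.7998 for glycolysis, 0.00461 to 0.860 for phagocytosis and 0.145 to 0.847 for stress genes. For cell types they were 1.01e-04 to 0.847 (rods), 0.0135 to 0.887 (cones), 0.370 to 0.706 (inner retinal neurons), 0.0283 to 0.797 (vascular), 0.226 to 0.894 (border-associated macrophages), 0.0491 to 0.860 (neutrophils) and 0.0286 to 0.839 (T and NK cells). The cause of these turns was not tested.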

Other observations

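The tests of oocyte, Y-linked, exchanged-label, monocyte and homeostatic explanations and the fits with the batch as a term were chosen after the results they bear on were seen, although one list of oocyte markers was written down before its values were looked at. The gene and list tests without the batch, the estimated correlation and the exact permutations were planned.

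The haemoglobin-negative libraries (flox 1, CKO 2 and CKO 3) shared a set of transcripts of the egg. Bcl2l10 stood at 41.2, 55.9 and 41.6 CPM there and at 0.429 to 1.39 CPM in the other 3, H1f8, the oocyte linker histone gene, at 23.2, 29.5 and 23.9 CPM, and Gdf9, an oocyte growth factor gene, at 21.9, 31.6 and 22.8 CPM. RNA or reads from oocytes carried into these libraries are a candidate explanation: in the second list of 24 markers, 22 were detected and 13 separated the libraries this way with 0 the other way, against 2.19% of 4833 genes of like level. The component 1 score of flox 1 minus the mean of the other flox libraries was -60.4, which goes against genotype as labelled, but only if the labels hold. With the labels of flox 1 and CKO 1 exchanged this split would be the genotype split. Cd36 was lower in each haemoglobin-negative library (log2 fold change -1.32, SE 0.40, adjusted p = 0.150 by edgeR with Benjamini-Hochberg adjustment). Exchanged labels were also predicted to give levels near 0 there, but these were 28.5 to 90.5 CPM. Counts per gene do not show whether a deleted exon is missing, so that level does not decide. Genotype, exchanged labels, batch and treatment, which no label used here gives per library, cannot be told apart here. Y-linked counts, which mark sex and not genotype, decide nothing.

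Y-linked counts in flox 2 and flox 3 were 7.02% and 20.4% of the flox 1 level, between those of flox 1 and the CKO libraries. The oocyte transcripts of flox 1 were at a median of 0% of their flox 1 level in both libraries. That median covered 32 markers, including the set picked after its values were seen, so its low value was partly built in. On the second list, Nlrp14 (45 counts in flox 1), Zar1 (49) and Mos (38) also had 0 counts in both libraries. Others of that list were present, such as Bmp15 (83, 18 and 39 counts in flox 1 to 3) and Tle6 (41, 22 and 26). The absent transcripts argue against carry-over of flox 1 reads at the Y-linked percents. All 4 Y-linked genes had 3 or more counts in both libraries, but Kdm5d also did in each CKO library (7, 6 and 14 counts). In flox 2 Kdm5d stood at 0.622 CPM, within the CKO range of 0.429 to 0.720 CPM, and so adds nothing there. Male cells or RNA of another source in flox 2 and flox 3 may account for their Y-linked counts. That cannot be told apart from a mixed pool of animals, because no label gives sex. The summed Y-linked level thus separated the labels, at 10.7 to 153 CPM in flox and 0.433 to 0.749 CPM in CKO, although Kdm5d alone overlapped. Sex stays an open explanation for any other difference between the labels.

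The monocyte list lay higher in the libraries labelled CKO with the preset correlation (adjusted p = 0.161 with an estimated correlation, and exact permutation p = 0.8 for its summed level), and Cx3cr1 lay lower without passing the test over all genes. A general loss of homeostatic microglial transcripts stays open. With the batch as a term the median log2 fold change of the other 21 homeostatic genes lay more than their SD above Cx3cr1 (-0.18, SD 0.48, against -1.09). In the main fit it did not (-0.39, SD 0.96, against -1.25). Cx3cr1 has the smallest p of this list and was named for it, and the SD is a spread between genes, so neither comparison decides. A larger share of monocytes, which the CD11b-intermediate gate should limit, may contribute, but 10 of the 14 markers were positive with the batch as a term and 4 negative, so it stays open. A driver allele placed in Cx3cr1 might lower that gene by about 1 log2 unit; the -1.09 averages within-batch ratios of -0.56 and -1.62, and the labels name no driver, so this cannot be told apart from a biological effect. The genotype, sex, animal and treatment explanations were not separated by any test here.

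Chance was examined through the 10 ways to split the 6 libraries into 3 and 3, too few for a share under 0.05. edgeR called 0 genes in the real split and 270 in the highest other; all 10 splits give at least 0 by construction, so this count tests nothing. DESeq2 called 23 genes in the real split and 942 in the highest other, and 3 splits reached 23 with the real one included. Camera with the preset correlation called 4 lists in the real split and 15 in the highest other, and all 10 splits gave at least 4. The split that called 270 and 942 genes is the one between haemoglobin-negative and haemoglobin-positive libraries. This batch was set after the data were seen and is the grouping of principal component 1. Its high counts therefore describe that structure of the samples and are not separate support for it. The monocyte list had its smallest camera p in the real split (9.58e-09, against 0.00805 to 0.910 in the other 9), but with an estimated correlation its adjusted p there was 0.161 and 0 lists passed in any split.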
